A study of Homo sapiens with 6 samples.

How the data were processed

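RNA sequencing measured gene expression in 6 libraries, 3 labelled GCA and 3 labelled CON, each a separate sample in the labels. The series' title names glycocholic acid, a glycine-conjugated bile acid, and GCA is read here as that compound. Per the labels, cells of a colorectal cancer line called MC38 were grown for 24 hours with or without GCA, and its dose is not given in the sources used here. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. MC38 is known as a mouse line, while the labels give human as the organism and hg38 as the build, and both tables list human gene symbols. The labels' extraction protocol also speaks of heart samples, and the labels name both polyA RNA and a stranded total RNA kit with ribosomal RNA depletion. These conflicts were left as they stand. The titles of the 3 GCA samples read fa, a name the sources used here do not explain, while their treatment label is GCA. Table columns were matched to samples by these titles and groups taken from the treatment label, so every GCA value rests on that label being right for the fa samples.

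The authors deposited a table of raw counts per gene for 16229 gene symbols. They also deposited a table of FPKM values for the same genes. The submitters' processing notes name fastp 0.20.1, HISAT2 2.2.1.0, HTSeq 0.11.2 and the build hg38, without saying which step used which. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Each deposited FPKM value equals the gene's count divided by the library's total count and a single length per gene, within a relative tolerance of 1e-09, for 16229 of 16229 genes. The FPKM table therefore adds no independent measurement. Every gene had at least 1 count in total over the 6 libraries, 15913 symbols matched a protein-coding symbol of NCBI's annotation of GRCh38.p14, and no mitochondrially encoded gene is among them. Gene coordinates are from that annotation. GC content came from GENCODE release 29 transcripts, by symbol for 15801 genes and by an older symbol or identifier for 305, which covered 99.2% of the table.

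Total counts per library ran from 18057453 to 20531612. A floor of 3 counts in a library corresponded to 0.146 to 0.166 CPM (counts scaled to library size), and such floors cover counting error only. No 2 libraries of a group agreed within sampling noise: the chi-square per gene between 2 libraries of a group ran from 4.9 to 47. Between replicates 2 and 3 it was 4.9 in CON and 6.7 in GCA. Pairs with replicate 1 gave 41.5 and 47 in CON and 24 and 21.1 in GCA.

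The comparison of GCA with CON used edgeR 4.0.16 in R 4.3.3 on the raw counts, with TMM normalization, filterByExpr (minimum count 10, minimum total 15), glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. Gene lists were tested with limma 3.58.1 (camera, preset inter-gene correlation 0.01) on log2 CPM with a prior count of 2, for lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the 33 lists tested. The comparison, the test, 39 gene lists, the rule for named genes and all but 3 of the alternatives were fixed before the data were examined. The rule named the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping groups and a mean log2 CPM of at least 1. It added the 4 members with the lowest p of each list past the threshold and of the lists on FXR targets, bile acid receptors, antigen presentation and checkpoint ligands, the 2 most abundant markers of each other cell type, and NR1H4, GPBAR1, RXRA and CD274. Some genes that the rule takes are not reported here.

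The replicate numbers in the labels were checked for pairing: the deviations from the group means of same-numbered libraries correlated across genes at 0.206, 0.137 and 0.104, each over the limit of 0.1 set beforehand. Genes are not independent replicates in such a correlation. Differently numbered libraries were not compared in this way, so the limit of 0.1 cannot show that a pairing is real. By that limit the numbers were taken to pair the samples, so fits with the replicate number as a block stand beside the results they change. That limit alone decided this, although a count of calls with the block had been seen by then. The fit without the block stayed the main one.

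The alternatives were other normalizations (DESeq2's size factors, upper quartile, library size only), other filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate block, and leaving out each library. For lists they also included camera with an estimated correlation and fry. Camera asks whether a list's members rank higher or lower than the other genes. Fry asks whether the members themselves changed, so a call by fry answers a different question. A correction for GC content and gene length (medians of 20 bins removed per library in 3 rounds, as offsets in the edgeR fit), the same with the block, and leaving out replicate 1 of both groups were added after the data were seen.

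The edgeR fit was tested on simulated GCA and CON counts with 200 changed genes, over 12534 genes tested. It recovered 40% of the genes changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold and 8-fold, with 5 false calls. With a simulated trend in GC content and length in 2 CON libraries, over 12539 genes tested, 18% of the genes changed 1.5-fold and 62% of those changed 2-fold were recovered with 29 false calls. After the correction these were 52% and 90% with 22 false calls. In the data the trend followed the groups: deviations correlated with GC content at -0.13, -0.54 and -0.51 in CON and 0.51, 0.25 and 0.49 in GCA. A trend of that kind was not simulated, so these counts cannot show how many false calls it makes or how well the correction removes it. Another simulation over 12539 genes drew the genes independently of each other. In it a list of 20 genes raised 1.5-fold, tested with 200 random lists, passed with the preset correlation (adjusted p = 1.98e-24) but not with an estimated one (adjusted p = 0.0613).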

Results

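The data comprised 6 RNA-seq libraries of a colorectal cancer line, 3 from cells kept for 24 hours with GCA and 3 from control cells without it (CON). The design asks what this bile acid does to the cells' transcriptome. Total counts were 19110987, 18057453 and 18410261 in CON 1 to 3 and 20531612, 19826305 and 19484569 in GCA 1 to 3. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, those of gene lists from camera, and n = 3 per group throughout.

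A small set of genes stood far higher in GCA than in CON. SOX14, a SOX-family transcription factor gene (chromosome 3, 137764315 to 137766334, GRCh38), went from 0.440 ± 0.0952 CPM (SD) in CON to 437 ± 82.9 CPM in GCA. Its counts were 6, 9 and 10 in CON and 6940, 9087 and 9626 in GCA (log2 fold change 9.93 ± 0.25, SE; adjusted p = 5.98e-11). CD274, which encodes the checkpoint ligand PD-L1 (chromosome 9, 5450542 to 5470554), went from 1.63 ± 0.348 to 306 ± 83.6 CPM, a rise of 7.55 ± 0.26 on the log2 scale (adjusted p = 1.29e-09). AQP3, a water and glycerol channel (chromosome 9, 33441160 to 33447593), rose 58.5-fold to 505 ± 120 CPM (adjusted p = 1.29e-09). ZDHHC9, a palmitoyltransferase gene (chromosome X, 129803288 to 129843886), rose 41.5-fold to 1823 ± 215 CPM (adjusted p = 3.98e-10).

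The next largest rises by the naming rule were SERPINA3, MIA, PRR15L, PPP1R1B, GRHL3 and IFI27. The acute-phase protease inhibitor gene SERPINA3 rose by 5.32 ± 0.40 on the log2 scale (adjusted p = 2.38e-06), from 0.628 to 25.7 CPM. The epithelial transcription factor gene GRHL3 rose by 4.23 ± 0.21 (adjusted p = 9.18e-08), and the other 4 rose by between 4.19 and 4.89. APOL3, ISLR and RNF222, outside the rule and picked after their values were seen, had 0 counts in each CON library and 12 to 24 in each GCA library, so their fitted folds are not given.

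Falls were smaller. DDIT3, which encodes the stress transcription factor CHOP (chromosome 12, 57516588 to 57520517), fell by 2.14 ± 0.39 on the log2 scale (adjusted p = 0.00122). Its CON level varied, with counts of 256, 607 and 1098 against 102, 170 and 183 in GCA. GPAT3, an acyltransferase of glycerolipid synthesis, fell by 2.08 ± 0.14 (adjusted p = 1.12e-06), and GALNT5, ARRDC3 and SLC43A1 fell by 1.96, 1.83 and 1.52. Also among the 10 largest falls by the rule were the DNA repair genes EXO1, which fell by 1.51, and PARP2, which fell by 1.49. PAX6 fell by 1.47, ZGRF1 by 1.54 and IFRD1 by 1.46, each log2; the ZGRF1 call was lost without CON 2 (adjusted p = 0.0547) and both the ZGRF1 and IFRD1 calls were lost on unfiltered log2(FPKM + 1).

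In all, 4584 of 12604 tested genes (36.4%) passed the threshold, 2307 higher and 2277 lower in GCA. Of these, 838 changed by at least 1 on the log2 scale, 657 up and 181 down. The groups did not overlap in 6108 tested genes, where chance gives 10%. Fold changes correlated across genes with GC content (r = 0.48), and with the GC and length correction 3691 genes passed, 1413 higher and 2278 lower, with 53.4% of the original calls kept in the same direction. Leaving out 1 library gave between 2621 calls (without GCA 3) and 6707 (without CON 1), with 3029 without CON 2.

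**Figure D1:**
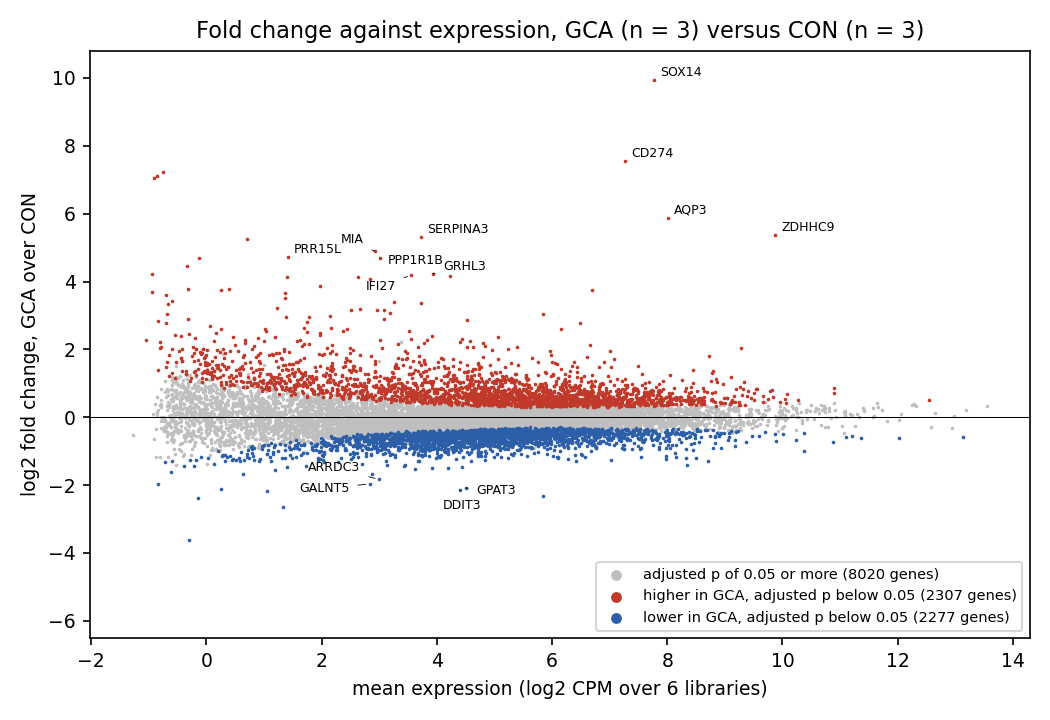
Log2 fold change of GCA over CON against mean expression (log2 CPM over the 6 libraries) for the 12604 tested genes, 1 point per gene, coloured by direction and adjusted p. SOX14, CD274, AQP3 and ZDHHC9 stand above 5 at high expression, while the labelled falls lie between -1.83 and -2.14; the 3 points near 7 at low expression are genes with 0 counts in each CON library.

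**Figure D2:**
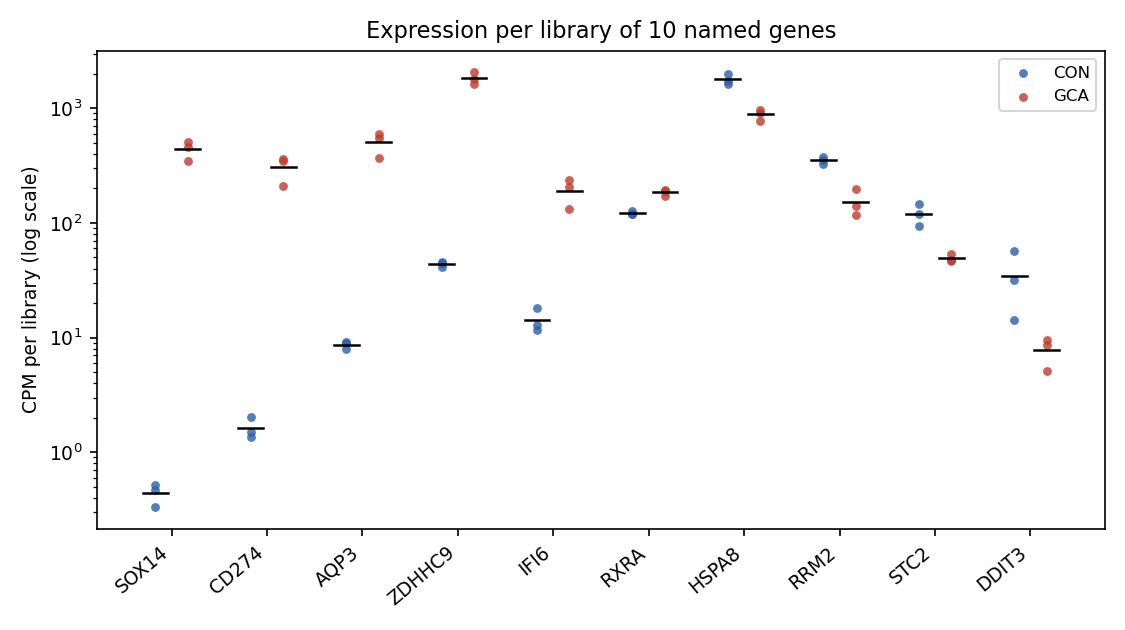
CPM per library on a log axis for 10 named genes, with CON in blue, GCA in red and a bar at each group's mean (n = 3). SOX14 lies below 1 CPM in each CON library and at a mean of 437 CPM in GCA; DDIT3 varies most within CON.

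The receptors and target genes of bile acids showed no call as groups. NR1H4, which encodes the nuclear bile acid receptor FXR, was not analysed here, and GPBAR1, the gene of the membrane bile acid receptor, had 2, 0 and 3 counts in CON and 6, 0 and 3 in GCA, below the filter. Of the 24 genes in the list of FXR targets, 16 had a row and 7 passed the filter. Of these 7 tested genes 4 rose, also when adjusted over the list alone (list adjusted p = 0.126). The FXR targets NR0B2, SLC51A, SLC51B and ABCB11 stayed below the filter in both groups. Their means were 0.0173, 0, 0 and 0.0173 CPM in CON and 0.0349, 0.0349, 0.0675 and 0 CPM in GCA. The bile acid exporter genes ABCC3 and ABCC2 rose by 1.21 ± 0.23 and 1.05 ± 0.19 on the log2 scale (adjusted p = 0.00182 and 0.00137). FGF19, an intestinal FXR target, had a log2 fold change of 0.16 (adjusted p = 0.506). The lipoprotein genes PLTP (0.75) and APOE (1.01) passed the test too, but not with the GC and length correction, which left log2 values of 0.32 and 0.38; the APOE call was also lost without CON 2, GCA 2 or GCA 3 (adjusted p from 0.0573 to 0.114). Of the bile acid receptors and their partners, 3 of 8 tested genes rose, also over the list alone (list adjusted p = 0.154). RXRA, the shared partner of FXR and LXR, rose from 122 ± 4.70 to 185 ± 11 CPM (log2 0.60 ± 0.11, adjusted p = 0.00167). With the correction RXRA stood at 0.23 (adjusted p = 0.0693; 3.85e-06 to 0.0693 over its alternatives). NR1H2 had a log2 value of 0.35 that passed narrowly (adjusted p = 0.0434) and turned to -0.08 with the correction. It also lost its call when CON 2, CON 3, GCA 2 or GCA 3 was left out, with library size alone and without the filter. NR1H3 had 0.34 (adjusted p = 0.104), which passed with the replicate block (adjusted p = 0.0377) and without CON 1 (0.00524) and stood at 0.10 with the correction (adjusted p = 0.572; 0.0047 to 0.572 over its alternatives). Both lists passed with fry (adjusted p = 0.0498 for FXR targets and 0.0139 for receptors), but not with an estimated correlation (adjusted p = 0.55 and 0.50). With the GC and length correction the FXR median went from 0.75 to 0.32 (adjusted p = 0.403) and the receptor median from 0.25 to -0.07 (adjusted p = 0.751).

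Targets of the sterol receptor LXR rose as a list. Of 10 tested members 7 rose and none fell (adjusted p = 0.000924; adjusted p = 0.29 with an estimated correlation). The cholesterol exporter gene ABCG1 rose by 1.97 ± 0.23 on the log2 scale, from 2.33 to 9.15 CPM (adjusted p = 6.85e-05). SREBF1, the gene of the lipogenic factor SREBP1, rose by 0.90 from 429 to 802 CPM, and LPCAT3, a phospholipid-remodelling enzyme, by 0.56. With the GC and length correction the list's median went from 0.80 to 0.42 and still passed (adjusted p = 0.000421), SREBF1 stood at 0.46, and the members PLTP and APOE lost their calls. The lists of cholesterol synthesis (4 of 26 rose, 1 fell; adjusted p = 0.574) and fatty acid synthesis (3 of 15 rose, 2 fell; adjusted p = 0.851) did not pass, and the sign of their medians depends on the scaling. The list of retinoid and RXR partner targets passed on 4 of 11 tested genes (adjusted p = 0.00925; adjusted p = 0.29 with an estimated correlation). These were STRA6, a retinol transporter (4.13 ± 0.38), CRABP2, which binds retinoic acid (2.03 ± 0.16), the vitamin D hydroxylase CYP24A1 (1.47) and the transglutaminase TGM2 (1.41). CRABP2 reached 999 ± 151 CPM, from 245 ± 39.2. In the lysosome and autophagy list 8 of 25 genes rose and 1, the cholesterol transporter NPC1, fell by 0.55 (adjusted p = 0.0349; adjusted p = 0.50 with an estimated correlation). NEU1, CTSB and CTSD, which encode lysosomal hydrolases, rose by 1.17, 1.13 and 1.09, and the autophagy gene GABARAPL1 by 0.78. With the correction CTSD stood at 0.62 and the list's median went from 0.29 to 0.14. This list's call was lost without CON 1 (adjusted p = 0.0986).

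Interferon-stimulated genes gave the lowest list p. Of 22 tested members 20 rose and none fell, with a median log2 fold change of 1.52 (adjusted p = 2.61e-12; adjusted p = 0.29 with an estimated correlation). IFI6 rose 13.5-fold from 14.2 ± 3.34 to 192 ± 53.1 CPM (adjusted p = 5.85e-07). OAS1, a sensor of double-stranded RNA, rose by 4.12 ± 0.26, IFIT1 by 3.16 ± 0.21 and IFI27 by 4.19 ± 0.30 on the log2 scale. The interferon-induced chemokine CXCL10 stayed below the filter, with means of 0.0173 CPM in CON and 0 in GCA. In MHC class I antigen presentation 14 of 18 genes rose and none fell (adjusted p = 8.14e-07; adjusted p = 0.26 with an estimated correlation). PSMB9, an immunoproteasome subunit, rose by 2.06 ± 0.18, HLA-F by 1.12 ± 0.15 and the peptide-loading factor TAPBP by 0.98 ± 0.12. HLA genes share sequence, so reads can be split between them and their single values are uncertain.

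Checkpoint ligands and suppressive surface proteins rose as a list, with 10 of 16 tested genes up and 3 down (adjusted p = 0.00461; adjusted p = 0.44 with an estimated correlation). CD274 led it. VSIR, which encodes the inhibitory ligand VISTA, rose by 1.54 ± 0.15 from 21.6 to 63.0 CPM (adjusted p = 1.40e-05), and LGALS9, the galectin-9 gene, by 2.34 ± 0.34 from 0.565 to 2.90 CPM. TNFSF9 rose by 0.80 (adjusted p = 0.000244); its product is known as a costimulatory ligand, not a suppressive one. PVR, NECTIN3 and FAS fell by 0.42, 0.50 and 0.59; FAS, a death receptor gene outside the naming rule, was picked after its values were seen (adjusted p = 0.0316). With the GC and length correction TNFSF9 stood at 0.46 and the list's median went from 0.59 to 0.32.

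**Figure D3:**
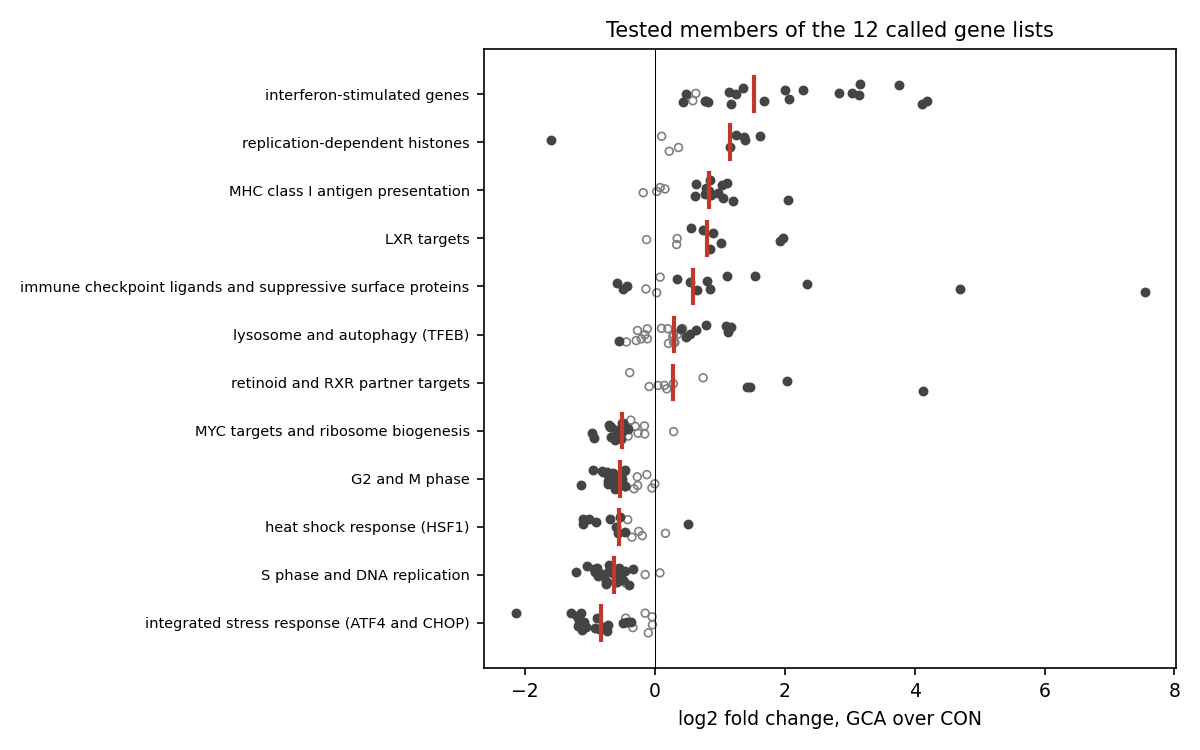
Log2 fold change of GCA over CON (horizontal axis) for each tested member of the 12 lists past the threshold; filled points passed the gene's own test, open points did not, and red bars mark the median. The median is 1.52 for interferon-stimulated genes and -0.82 for the integrated stress response; vertical scatter within a list carries no value.

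Targets of the integrated stress response and heat shock genes fell as lists, while 3 other stress lists did not pass. Of 28 tested targets of the integrated stress response (ATF4 and CHOP) 21 fell and none rose (adjusted p = 2.94e-07; adjusted p = 0.50 with an estimated correlation). STC2 fell by 1.29 ± 0.15, the glutathione-degrading enzyme gene CHAC1 by 1.17 ± 0.14, SESN2 by 1.09 ± 0.14 and ATF3 by 1.13 ± 0.16 on the log2 scale, each with an adjusted p between 7.86e-05 and 0.000259. ATF4 itself fell by 0.49, from 1205 to 856 CPM. The heat shock list fell in 10 of 16 members, and HSPB1 alone rose (adjusted p = 0.00145; adjusted p = 0.55 with an estimated correlation). HSPA8, the constitutive HSP70 chaperone gene, fell by 1.01 ± 0.15 from 1783 ± 180 to 887 ± 106 CPM, HSPH1 by 1.12 ± 0.14, HSPA4L by 1.11 ± 0.17 and the mitochondrial chaperonin gene HSPD1 by 0.91 ± 0.13. HSPA1A (log2 0.16, adjusted p = 0.656), HSPA1B (-0.20, 0.446) and BAG3 (-0.25, 0.145), outside the naming rule, were among the 5 members that did not pass. The heat shock call was lost without replicate 1 of both groups (adjusted p = 0.089). The lists that did not pass were the unfolded protein response (5 of 22 fell, none rose; adjusted p = 0.169, and 0.0488 with fry), NRF2 targets (2 of 23 rose, 7 fell; adjusted p = 0.634) and hypoxia targets (1 of 24 rose, 5 fell; adjusted p = 0.368).

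The lists of S phase, of G2 and M phase and of MYC targets fell as well. In the S phase list 23 of 26 genes fell and none rose (adjusted p = 1.63e-07; adjusted p = 0.50 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 1.22 ± 0.17 from 354 to 152 CPM, the replication-licensing gene CDC6 by 1.05 ± 0.13, and CDC45 and MCM6 of the replicative helicase by 0.94 and 0.92. In the G2 and M phase list 18 of 26 fell and none rose (adjusted p = 1.04e-05; adjusted p = 0.50 with an estimated correlation). Cyclin A2 (CCNA2) fell by 0.95 ± 0.13, BUB1 by 0.73, KIF23 by 0.72 and HMMR by 0.71, while PLK1 had a log2 value of -0.32 (adjusted p = 0.221). With the correction BUB1, KIF23 and HMMR fell by 0.47, 0.45 and 0.46. In the list of MYC targets and ribosome biogenesis 18 of 26 fell and none rose (adjusted p = 1.37e-05; adjusted p = 0.50 with an estimated correlation). ODC1, the rate-limiting enzyme of polyamine synthesis, fell by 0.98 ± 0.14 and MYC itself by 0.50, and POLR1B, LYAR and WDR12 fell by 0.68, 0.69 and 0.61; WDR12 fell by 0.35 with the correction. Adjusted over the list alone, 11 heat shock, 24 S phase, 19 G2 and M phase and 21 MYC list genes fell; in the other 8 lists past the threshold the counts did not change. Replication-dependent histones moved up, 5 of 9 rising and 1 falling (adjusted p = 0.0389; adjusted p = 0.50 with an estimated correlation). H1-2 rose by 1.62 ± 0.21, H2BC5 by 1.39, H2AC6 by 1.26 and H2BC21 by 1.15, while H1-4 fell by 1.60. Most mRNAs of this class lack a polyA tail, and the labels name both polyA RNA and a total RNA kit, so what these counts measure depends on which was used. The list summed to 22.4 CPM in CON and 54.5 CPM in GCA, genes within a core histone family can share reads, so their single values are uncertain, and the list's call was lost without CON 2, CON 3 or GCA 2 (adjusted p from 0.0613 to 0.0731). The H2BC21 call was lost without GCA 3 (adjusted p = 0.064).

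The other 21 lists tested had adjusted p-values from 0.0959 to 0.956. TGF-beta targets had the lowest of these (5 of 18 rose, 2 fell); they passed with the replicate block (adjusted p = 0.0313), without CON 2 (0.0416) and without GCA 1 (0.0312), but not with the block and the GC and length correction together (0.285) or an estimated correlation (0.70). The correction alone took their median from 0.15 to 0.01 (adjusted p = 0.451). In it SMAD6 rose by 2.10 ± 0.16 and ID2 by 0.75. The list of epithelial and intestinal differentiation had 6 of 16 genes up and 3 down (adjusted p = 0.286). The p53 list had 4 of 26 genes up and 9 down (adjusted p = 0.12), with BBC3 up by 0.91 and CDKN1A and MDM2 down, having fallen by 0.85 and 0.77. The list passed without CON 1 (adjusted p = 0.024), and so did immediate early genes (0.024), oxidative phosphorylation (0.000255) and cytosolic ribosomal proteins (0.00742, and 0.0115 without GCA 1). With an estimated correlation over all 6 libraries the adjusted p was 0.69 for the p53 list and 0.81 for each of the other 3. The correction took the medians of oxidative phosphorylation and ribosomal proteins from 0.15 and 0.13 to -0.06 and -0.01. CON 1 stood apart from CON 2 and 3 on the second principal component (18.1% of variance), at 34.5 against -14.7 and -17.8. GCA 1 lay to the same side of GCA 2 and 3, at 8.1 against -5.8 and -4.3. The first component (65.7%) parted GCA from CON.

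Lists of markers of other cell types had too few tested genes for a test, with 2 to 4 each, and low levels. Leukocyte markers summed to 33.4 CPM in CON and 40.1 CPM in GCA and cardiomyocyte markers to 26.6 and 40.7, and the sums of hepatocyte, erythroid, and fibroblast and endothelial markers were lower in both groups. Of their most abundant genes, CORO1A rose by 1.16 (0.72 with the GC and length correction), SERPINA1 by 1.76 and VWF by 1.43. Outside the rule and picked after its values were seen, the leukocyte marker S100A9 rose from counts of 2, 2 and 1 in CON to 14, 19 and 23 in GCA (adjusted p = 0.000706). Its CON counts lie under the floor of 3, so its fitted fold is not given. COL1A1 (0.44), TNNI3 (0.68) and HBA2 (0.76) passed the test but lost it with the correction. The HBA2 call was also lost without CON 2, CON 3, GCA 1 or GCA 2, and the COL1A1 call without any of these or GCA 3. CPS1, HBB, CD68 and MYL2 did not pass, although CD68 did without GCA 1 (log2 -0.54) and MYL2 did on filtered log2 FPKM. HBA2 shares its sequence with HBA1, so its count is uncertain.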

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

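The GC and length correction, alone and with the block, and leaving out replicate 1 of both groups were tried after the data were seen; the cause of each difference below was not tested unless stated. Beside the 4584 calls, fits with libraries left out made 2621 to 7419 calls of their own, the highest without replicate 1 of both groups (4504 of them among the 4584, in the same direction); 1493 to 3710 were higher and 1128 to 3709 lower in GCA. Counts below or above the main one by over 1.5 times came without replicate 1 of both groups (7419; 3710 higher, 3709 lower), without GCA 3 (2621; 1493 and 1128) and without CON 2 (3029; 1297 lower), and for lower genes also without CON 1 (3482) and GCA 2 (1484). Fewer samples enter each of these fits. The correction called 1413 higher genes. Calls of at least 1 on the log2 scale numbered 838 (657 up, 181 down); in its own fit and gene set, limma on log2(FPKM + 1) made 267 (221 and 46), with no filter 265 (222 and 43), and with a pseudocount of 0.1 486 (377 and 109), on scales that shrink the change of low genes. The correction made 513 (401 and 112), and 519 with the block (409 and 110); overlaps of these with the 838 were not counted. Leaving out libraries gave 129 to 332 larger falls (323 without CON 1). Of the 33 lists tested, 12 passed with camera's preset correlation, 0 with an estimated one (4 at an unadjusted p under 0.05) and 19 with fry. The estimated correlation also missed a simulated list of 20 genes raised 1.5-fold (adjusted p = 0.0613), so a list that fails it may still have changed. The simulated genes were drawn independently of each other. Among the 12 lists that passed, the estimated correlation ran from -0.04 (LXR targets) to 0.54 (S phase), against the preset 0.01. The simulation therefore cannot show that the preset holds for these lists. For LXR targets (-0.04) and for retinoid and RXR partner targets (-0.03) the estimate lay below the preset. A correlation above the preset therefore does not account for the calls that these lists lost. NR1H2 turned to -0.08 with the correction, and to -0.08 with the block added. The replicate block called 5163 genes and 13 lists; besides NR1H3 and the TGF-beta list, paired fitting changed no other named call. Of 83 named genes tested, 78 passed, and 13 lost or gained a call under some of the 20 alternatives. DESeq2 kept 96.0%, limma-voom 96.8% and the library size alone 89.7% of the calls in the same direction. Leaving out mitochondrially encoded genes was not run, since the table lists none. Depth limits genes near 3 counts, or 0.146 to 0.166 CPM.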

Other observations

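The gene families here and the tests of mouse reads, neighbouring genes and another cell line were chosen after the results were seen. Family p-values are adjusted over the tested families alone. Some members, such as EXO1 and SERPINA3, had already been named for their change, so these p-values describe the families and are no independent test. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, fell in 17 of 20 tested genes (camera adjusted p = 5.55e-06; adjusted p = 0.20 with an estimated correlation), with IARS1 and WARS1 having fallen by 0.94 and 0.93 on the log2 scale. WARS1, GARS1 and AARS1 are also in the integrated stress response list. Homologous recombination and Fanconi anaemia genes fell in 20 of 27 (adjusted p = 1.19e-08; adjusted p = 0.11 with an estimated correlation). Among them BRCA1 fell by 1.43 ± 0.21, MMS22L by 1.40 ± 0.18 and RAD54L by 1.07 ± 0.13. Of the EGFR ligands, EREG fell by 1.41 ± 0.17 and AREG by 1.30 ± 0.21, and the 5 tested together did not pass (adjusted p = 0.0762).

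S100 genes, keratins, claudins and serpins rose as families, while the list of epithelial and intestinal differentiation, fixed before the data were examined, did not pass (6 of 16 rose, 3 fell; adjusted p = 0.286). S100 genes rose in 9 of 12 (adjusted p = 1.48e-05; adjusted p = 0.20 with an estimated correlation), among them S100A1 (4.07 ± 0.27), S100A3 (1.44 ± 0.21) and S100A9, which is also in the leukocyte marker list. Keratins rose in 8 of 17 (adjusted p = 0.00153; 0.20 estimated), with KRT80 up by 3.03 ± 0.18 and KRT13 by 1.56 ± 0.19. Claudins of tight junctions rose in 5 of 8 (adjusted p = 0.0107; 0.48 estimated), among them CLDN3 (1.94 ± 0.17) and CLDN4 (1.38 ± 0.14). With the GC and length correction the keratin median went from 0.70 to 0.23 and the claudin median from 0.97 to 0.51 (adjusted p = 0.0469 for each). Serpins rose in 8 of 15 and fell in 2 (adjusted p = 0.00421; 0.48 estimated); SERPINA3 and SERPINA1 rose while SERPINH1 fell by 0.49. MUC2, the main secreted intestinal mucin, fell from counts of 26, 14 and 35 in CON to 0, 4 and 2 in GCA (adjusted p = 0.00114). Its GCA mean of 0.103 CPM lies under the floor of 3 counts, so its fitted fold is not given. MT1F and MT1X, 2 of 4 tested metallothioneins, rose by 1.01 and 1.05. Proteasome subunits did not pass (2 of 37 rose, 7 fell; adjusted p = 0.125). Zinc finger genes had a median log2 value of -0.28, lower than other genes by camera (adjusted p = 0.00302; 0.48 estimated) but not with the GC and length correction (adjusted p = 0.0618). Of 357 tested zinc finger genes 33 were called up and 51 down, against 2307 and 2277 of all 12604 tested genes, and this difference in calls was not tested.

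SOX14, CD274, AQP3 and ZDHHC9 rose over 40-fold together, to between 306 and 1823 CPM. With the GC and length correction and the replicate block, the lowest of their 4 log2 fold changes was 5.46. The correction removes only the median of genes of like GC content or length, so it could hardly have undone rises of this size. The result shows that the trend shared by such genes is small beside these rises, and it weighs little otherwise. Gain or activation of the whole region is argued against by tested neighbours within 1 Mb, whose highest median over the 4 genes was -0.14. If the GCA libraries came from another cell line, genes would switch off as well. Of genes with 100 or more counts in each CON library, 0 had 10 or fewer in each GCA library. By the mirrored rule 1 gene was on in GCA and off in CON. The rules were set after the results, in which the lowest called log2 fold change was -3.62, so low counts were likely beforehand and weigh little. A response to GCA stays open as a hypothesis. So do copies of these genes added to the cells, or another line, such as a related one of the same origin, which gene counts cannot separate. Read coverage over untranslated regions would be informative and was not analysed here.

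Across genes, fold changes correlated with GC content at r = 0.48, and part of the 4584 calls may come from library bias in GC content and gene length. With the correction and the replicate block 58.6% of the calls were still made in the same direction, so the bias is not the whole cause, while the others were not. The lists that fell kept medians of -0.45 or lower (G2 and M phase the highest, S phase at -0.69), which argues against this bias for them. A true change that follows GC content would be removed by the correction too, so a GCA effect stays open for those others. Among the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 4584 genes in edgeR, the highest other gave 0 (24 to 989 genes at an unadjusted p under 0.05; at most 2 by DESeq2), as did the 3 others that part all 3 pairs, and 10 splits are too few for a share under 0.05.

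The libraries are labelled as a mouse line, yet the tables list human genes. If mouse reads had been aligned to the human genome, human genes without a mouse counterpart would be near 0. Of 21 genes listed as such from general knowledge, without an ortholog check, 10 (47.6%) reached 1 CPM in all 6 libraries. Among them were CD58 (5.55 to 9.63 CPM), IL32 (4.64 to 10.3 CPM) and CASP10 (2.41 to 4.49 CPM), which argues against mouse reads as the main source. MT1E, MT1X and APOL2, also among them, may have mouse relatives, so the share may be too high. A human line under the MC38 label is a candidate explanation; which line, and whether mouse cells were also present, was not tested.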
